A study of Spermophilus dauricus with 30 samples.

How the data were processed

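The data are RNA sequencing counts of 30 skeletal muscle libraries from Daurian ground squirrels in 5 states and 2 muscles, with 3 libraries in each of 10 groups. Per the labels' protocols, RNA was extracted with an AG RNAex reagent and libraries were made with the NEBNext Ultra RNA kit for Illumina. The deposited table holds raw counts per identifier and library, in whole numbers. Per the submitters' processing notes, HISAT2 2.0.4 and HTSeq 0.9.1 were used. The genome build, the annotation and the counting settings, strand included, are not given in the sources used here. Counts of near-identical copies and of overlapping or antisense genes could therefore have been split or merged, and the values of such genes are uncertain.

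The table has 27394 identifiers, of which 26378 are plain numbers and 1016 have a text prefix, and 4307 had no count in any library. The files do not pair identifiers with gene names. Before the data were examined, 32 gene lists and a panel of 18 genes had been fixed by symbol, for fibre types, metabolism, protein breakdown, other cell types and more. Of 759 symbols looked up, 0 matched an identifier, so the lists, the panel and their tests were not run. The rule for named genes asked for genes past an adjusted p of 0.05 with a gene symbol, a mean of at least 5 CPM over the 6 libraries compared and no overlap between the groups, with the largest rises and falls named. As no symbols were given, the same rule was used without the symbol. In HIB against SA it was met by 410 genes in SOL and 544 in EDL, and by 143 in both in one direction, of which 74 were higher and 69 lower. The 2 largest mean rises and the 2 largest mean falls of these are the identifiers given by number, and dropping the symbol and asking for both muscles were choices made after the files were seen.

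Depth ran from 31442362 to 41972200 counts per library, and 50 identifiers held 24.5% to 39.6% of a library's counts. At this depth the spread between libraries, more than counting error, limits the precision, except for genes of low counts. The typical coefficient of variation between libraries was 0.339 in SOL and 0.304 in EDL. No 2 replicates had identical columns, and the chi-square of replicate pairs ran from 54.6 to 418 times its degrees of freedom, so no library was counted as a duplicate. The labels give 3 numbered libraries per group without saying which animals they came from, so p-values measure the spread between these samples.

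Groups and replicate numbers come from the labels. Counts were analysed in R 4.3.3 with edgeR 4.0.16, using filterByExpr with its minimum count of 10, TMM normalisation and the quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. State comparisons used the 15 libraries of 1 muscle in 1 fit, so that all 5 states shared an estimate of the spread, with 16443 genes tested in SOL and 16299 in EDL. The muscle comparison and the tests of a difference between muscles used all 30 libraries and 16946 genes. The standard error of a log2 fold change is its size divided by the square root of its F value. Levels are TMM-normalised CPM, and principal components were taken from log2 CPM with a prior count of 2.

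The numbers 1 to 3 were checked as pairs from each library's deviations from its group mean over genes. Between the SOL and the EDL library of the same state and number the correlation was above 0.1 in all 15 pairs. It ran from 0.13 to 0.59 with a median of 0.44, and between different numbers the median was -0.20. Deviations from a group mean cancel out within the group. A positive correlation for same numbers thus forces a negative one between different numbers, which is no separate result. The best match of all 30 libraries in the other muscle had their own number. So the numbers pair SOL with EDL within a state, as read from the data, since the labels do not say so. Between states within a muscle, same-numbered libraries had a median correlation of -0.01, and numbers do not pair states.

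Alternatives fixed before the data were examined were DESeq2's size factors, no filter on low counts, DESeq2 1.42.0 with its Wald test, the replicate number as a block, the number within a state as a block, only the libraries of the compared groups, all 30 libraries in 1 fit, and leaving out each library. Added after seeing the data were fits without POST SOL replicate 1, sums of both muscles per number, thinned counts, further comparisons and tests of gene sets defined by the data. The set tests used camera in limma 3.58.1 with a preset correlation of 0.01 between genes, with an estimated correlation and fry beside it.

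The test was tried on simulated counts drawn from the real means, spread and library sizes, with 200 genes changed. For HIB against SA in SOL it recovered 1.49%, 14.9% and 77.3% of genes changed 1.5-fold, 2-fold and 4-fold, with 3 false calls among 16443 genes. For EDL it recovered 0%, 38.8% and 89.4%, with 1 false call among 16299. For SOL against EDL in SA it recovered 5.97%, 37.3% and 89.4%, with 1 false call among 16946. In these simulations changes of 2-fold or less were thus often missed at 3 libraries per group. They changed only genes above a low mean level, drew genes independently and called 65, 86 and 89 genes in all. The real comparisons called more genes, and these shares need not carry over to them.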

Results

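Skeletal muscle RNA of Daurian ground squirrels (*Spermophilus dauricus*), a small mammal that hibernates in bouts of torpor, was sequenced in 5 states of the yearly cycle. The states were summer activity (SA), before hibernation (PRE), hibernation (HIB), arousal between torpor bouts (IBA) and after hibernation (POST). Each state had 3 libraries labelled SOL and 3 labelled EDL, the usual abbreviations of the soleus and the extensor digitorum longus, giving 30 libraries in 10 groups. The libraries held between 31442362 and 41972200 counts and had counts for 17865 to 19488 identifiers. The identifiers are numbers, some with a text prefix, and the files do not pair them with gene names, so genes are described by how many moved, in which direction and by how much. At most 2 identifiers that rose and 2 that fell are given by their number.

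SOL and EDL libraries were told apart by their expression in every state. The first principal component of log2 CPM, read counts scaled to the library's size, carried 23.0% of the variance of the 30 libraries and parted SOL from EDL. A score was taken as the mean log2 CPM of the genes higher in SOL minus that of the genes higher in EDL, both sets from the SA libraries. In the other states it lay between -0.51 and 0.25 in the 12 SOL libraries and between -3.69 and -2.88 in the 12 EDL libraries. Within SOL, POST replicate 1 stood apart on the first component, at a score of -112 while the other 14 libraries lay between -19.6 and 66.9. Within EDL, the SA libraries lay between -53.2 and -39.3 on the first component and the HIB libraries between 37.8 and 42.4.

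**Figure D1:**
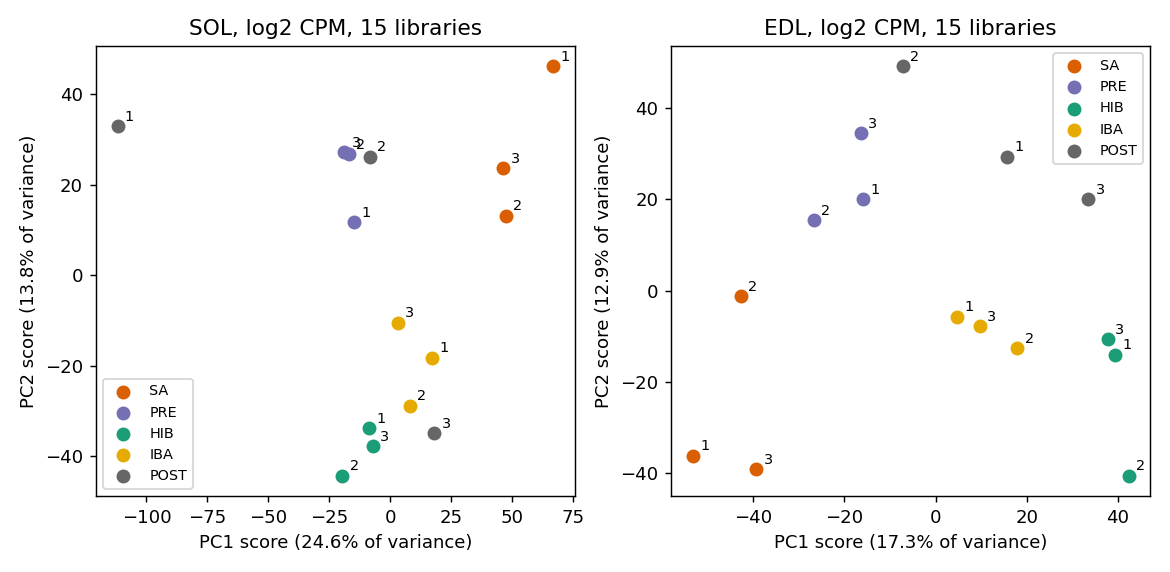
Scores of each library on the first and second principal components of log2 CPM, for 15 SOL libraries (left) and 15 EDL libraries (right), with the state as colour and the replicate number beside each point. POST SOL replicate 1 lies at -112 on the first component of SOL, and the HIB and SA libraries of EDL lie at opposite ends of its first component.

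Hibernating animals were compared with summer active ones in each muscle. In SOL, 591 of 16443 genes tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood test. Of these, 269 were higher in HIB, with a median log2 fold change of 1.11, and 322 were lower, with a median of -1.47. More than 2-fold changes were found for 151 of the higher genes and 254 of the lower genes. The 3 HIB libraries did not overlap the 3 SA libraries for 589 of the 591 genes, while 36.9% of all tested genes met that condition and chance gives 10%. The SOL count fell without single libraries: to 68, 6 and 26 without HIB replicates 1, 2 and 3, and to 75, 179 and 12 without SA replicates 1, 2 and 3. It rose to 1616 when POST SOL replicate 1, which is in neither group but shares the estimate of spread, was left out.

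In EDL, 780 of 16299 genes passed the same test between HIB and SA. The 418 genes higher in HIB had a median log2 fold change of 1.26 and the 362 lower genes a median of -1.07. More than 2-fold changes were found for 257 of the higher and 206 of the lower genes. In EDL the count was 163, 256 and 197 without HIB replicates 1, 2 and 3, and 144, 416 and 89 without SA replicates 1, 2 and 3.

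The HIB against SA changes of the 2 muscles ran in the same direction. Among 16007 genes tested in both muscles, 114 were called higher in both and 89 lower in both, and 0 were called in opposite directions. Independent lists of the same sizes would share 6.83 and 6.93 genes. Of the genes called in SOL, 98.1% had a fold change of the same sign in EDL, and of those called in EDL, 97.2% had the same sign in SOL. Over all 16007 genes the share of equal sign was 75.1%, and the fold changes correlated at r = 0.64, where genes are not independent replicates. Same-numbered SOL and EDL libraries of a state deviate together, so some of this agreement comes with any grouping of the libraries. The 9 other splits of the 6 same-numbered pairs of libraries gave r from 0.34 to 0.58 and a covariance of at most 0.129, against 0.329 for the real split. A test of the difference between the muscles called 0 genes in edgeR and 0 in DESeq2. At an unadjusted p under 0.05 there were 773 of 16946 genes (4.56%), in a fit that ignores the pairing. With same-numbered libraries paired, edgeR also called 0, with 1713 at an unadjusted p under 0.05, more than chance gives on average.

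**Figure D2:**
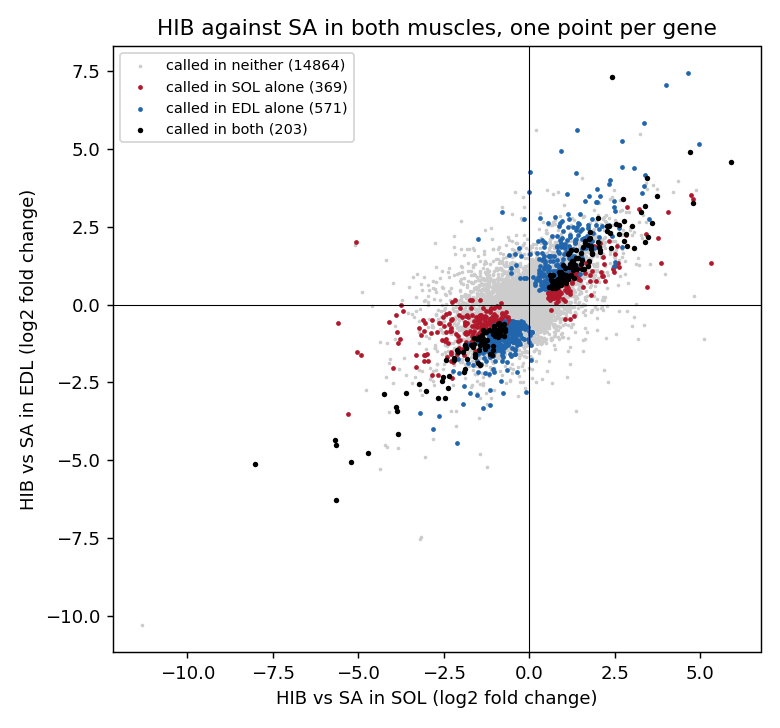
Log2 fold change of HIB against SA in SOL (horizontal) and in EDL (vertical), one point per gene tested in both muscles, coloured by the muscle in which the gene passed an adjusted p of 0.05. The 203 genes called in both muscles lie in the quadrants of equal sign.

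The identifiers with the largest mean rise and fall in both muscles were followed through all states. Identifier 101963904 rose from 7.24 ± 1.4 CPM in SA to 57.6 ± 37.3 CPM in HIB in SOL (SD, n = 3 each), a log2 fold change of 2.99 ± 0.50 (SE, edgeR adjusted p = 0.0162). In EDL it rose from 6.52 ± 1.49 to 37.7 ± 9.19 CPM, by 2.53 ± 0.29 (edgeR adjusted p = 0.00225). Its PRE levels were 15.3 ± 4.66 CPM in SOL and 23.0 ± 6.26 in EDL, its IBA levels 19.3 ± 10.1 and 24.2 ± 6.36, and its POST levels 10.5 ± 4.52 and 9.44 ± 2.03. In SOL its call was lost without HIB replicate 2 or SA replicate 3, and in EDL it held without any single library. Its log2 fold change then ran from 2.33 to 3.29 in SOL and from 2.35 to 2.72 in EDL. Identifier 101956544 rose by 2.01 ± 0.48 in SOL (edgeR adjusted p = 0.0381) and by 2.78 ± 0.60 in EDL (edgeR adjusted p = 0.0265). Its SOL level was 22.0 ± 4.07 CPM in SA, 14.7 ± 6.86 in PRE, 88.3 ± 52.5 in HIB, 43.0 ± 10.9 in IBA and 70.4 ± 32.2 in POST. In EDL it was 9.44 ± 3.84 CPM in SA, 9.32 ± 4.27 in PRE, 64.8 ± 64.0 in HIB, 22.8 ± 3.32 in IBA and 23.9 ± 11.2 in POST.

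Identifier Novel00382 fell by 5.64 ± 1.13 on the log2 scale in SOL (edgeR adjusted p = 0.0226) and fell by 6.27 ± 1.42 in EDL (edgeR adjusted p = 0.0293). Its 3 SA libraries spread widely, from 2.0 to 47.1 CPM in SOL and from 3.81 to 47.0 CPM in EDL. Replicate 1 was lowest and replicate 2 highest in both muscles, so the 2 falls are not independent results. Its HIB levels were 0.445 ± 0.261 CPM in SOL and 0.249 ± 0.197 in EDL. These came from only 8 to 22 and 2 to 19 counts per library. Its PRE levels were 10.2 ± 6.82 CPM in SOL and 6.79 ± 6.43 in EDL. In IBA it stood at 1.48 ± 1.08 and 2.79 ± 3.87 CPM, and in POST at 3.04 ± 2.93 and 6.94 ± 4.71. Identifier 101973010 fell by 5.22 ± 1.14 in SOL (edgeR adjusted p = 0.0302) and fell by 5.07 ± 1.21 in EDL (edgeR adjusted p = 0.0326). It stood at 65.5 ± 45.7 CPM in SA and 1.76 ± 0.295 in HIB in SOL, and at 94.9 ± 72.3 and 2.86 ± 3.33 in EDL. Its PRE means, 11.9 ± 4.93 CPM in SOL and 16.6 ± 4.21 in EDL, already lay below those of SA. The log2 differences were -2.46 and -2.51, without passing (edgeR adjusted p = 0.189 and 0.297). Its IBA levels of 26.7 ± 39.2 and 21.7 ± 27.9 CPM rested on replicate 3, at 72.0 and 53.9 CPM. Its POST levels were 91.5 ± 82.6 CPM in SOL and 44.3 ± 33.6 in EDL. In SA, replicate 2 was lowest and replicate 3 highest in both muscles, so these 2 falls are not independent either. For 101956544, Novel00382 and 101973010, leaving out 1 library ended the call in 5 of 6 cases each in SOL. In EDL it did so in 4, 5 and 4 of 6 cases. The direction was kept each time, which the rule of no overlap between the groups all but fixed. The size moved: in SOL the log2 fold changes of the 3 ran from 1.49 to 2.37, from -6.19 to -4.43 and from -5.63 to -4.57, and in EDL from 1.57 to 3.19, from -7.01 to -4.69 and from -6.66 to -4.48. With the spread taken from the 6 compared EDL libraries alone, the calls of 101956544 (edgeR adjusted p = 0.0752) and 101973010 (edgeR adjusted p = 0.0590) were lost.

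**Figure D3:**
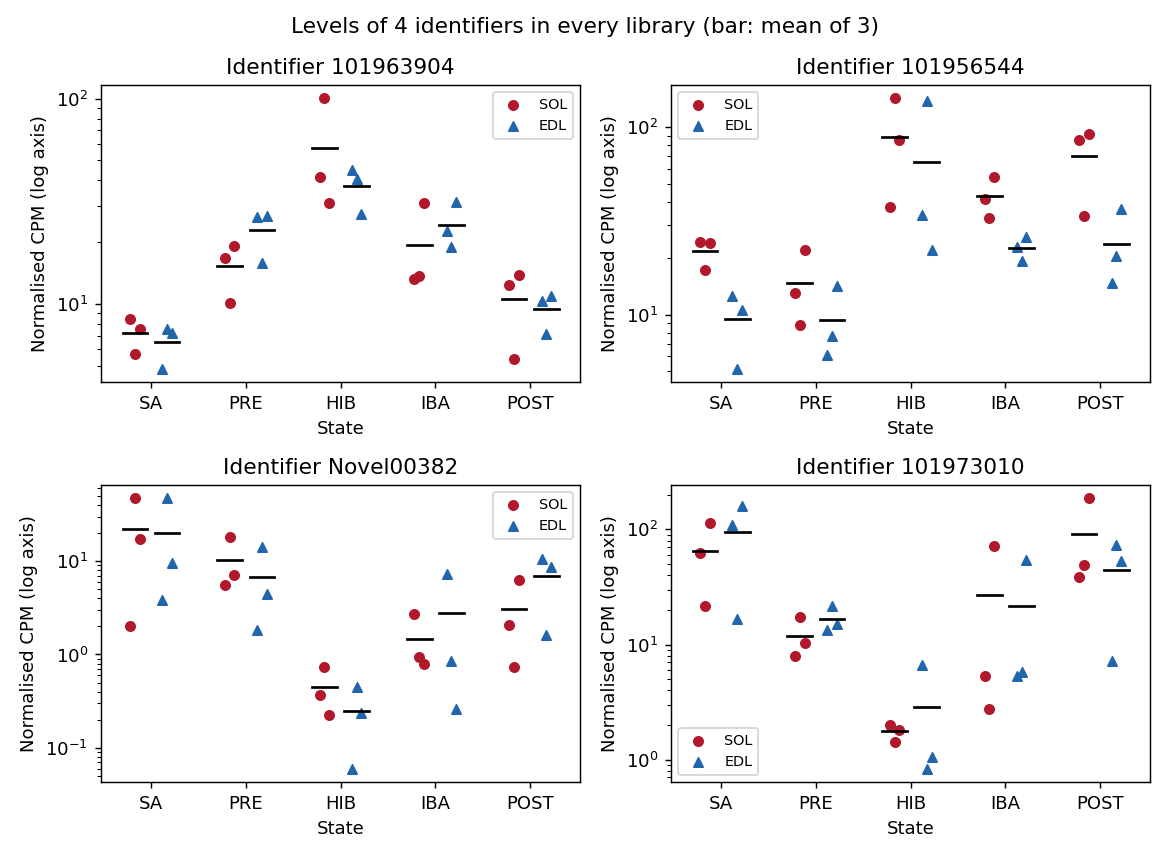
Normalised CPM on a log axis of 4 identifiers in every library, by state, with SOL as circles, EDL as triangles and the mean of 3 libraries as a bar. Identifier 101963904 has its highest means in HIB (57.6 CPM in SOL and 37.7 CPM in EDL) and Novel00382 its lowest (0.445 CPM in SOL and 0.249 CPM in EDL).

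The step into hibernation was split at the PRE animals. Between PRE and SA, 9 genes were called in SOL, 4 higher and 5 lower in PRE, all more than 2-fold. At an unadjusted p under 0.05 there were 3343 genes (20.3%). In EDL 0 genes were called by edgeR, with 2366 (14.5%) at an unadjusted p under 0.05 and 539 by DESeq2. The SOL count was 1 without any of the PRE replicates or SA replicate 3, 2 without SA replicate 1 or 2, and 979 without POST SOL replicate 1. The EDL count became 1 without SA replicate 1 and 58 without SA replicate 2, and stayed at 0 without any other. Identifier 101963904, called higher in HIB than SA, stood 1.82 ± 0.28 higher on the log2 scale in PRE than in SA in EDL, without passing the threshold (edgeR adjusted p = 0.0722).

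Between HIB and PRE, 119 genes were called in EDL, 59 higher and 60 lower in HIB, with median log2 fold changes of 1.33 and -1.26. In SOL 6 were called, 1 higher and 5 lower. Of the genes called in EDL, 99.2% had a fold change of the same sign in SOL, against 77.6% of all 16007 genes. The fold changes of the muscles correlated across genes at r = 0.70, and at 0.44 to 0.56 in the 9 other splits of the paired libraries, with a covariance of 0.254 against at most 0.120. Identifier 101956544 rose by 2.80 ± 0.60 between PRE and HIB in EDL (edgeR adjusted p = 0.0483) and stood 2.59 ± 0.49 higher in SOL (edgeR adjusted p = 0.114). The EDL count was 8, 2 and 28 without PRE replicates 1, 2 and 3, and 4, 10 and 41 without HIB replicates 1, 2 and 3. The SOL count was 2 without PRE replicate 1, 12 without POST SOL replicate 1, and 0 without any of the other PRE or HIB replicates.

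Arousal between bouts was compared with hibernation. Few genes passed: 5 in EDL, 3 higher and 2 lower in IBA, and 0 in SOL by edgeR. In SOL 1090 genes (6.63%) had an unadjusted p under 0.05 and DESeq2 called 41, and in EDL 1704 (10.5%) had one and DESeq2 called 134. In EDL the 3 higher genes had log2 fold changes of 1.76 to 3.64 and the 2 lower genes of -1.67 to -1.45, and all 5 had the same sign in SOL, as did 71.9% of all 16007 genes. The correlation of the muscles' fold changes across genes, r = 0.56, was below the 0.58 of another split of the paired libraries, while their covariance was 0.134, against at most 0.105 in the 9 other splits. Without HIB replicate 1 or 3, or IBA replicate 1 or 3, 1 gene was called in EDL, without HIB replicate 2 there were 2, and without IBA replicate 2 there were 6. None of the 4 followed identifiers passed: 101963904 stood at -1.58 ± 0.47 in SOL (edgeR adjusted p = 0.601) and -0.64 ± 0.27 in EDL (edgeR adjusted p = 0.429). The test of a difference between the muscles called 0 genes by edgeR and 0 by DESeq2. At an unadjusted p under 0.05 there were 175 (1.03%), fewer than chance gives on average, in a fit that ignores the pairing. With same-numbered libraries paired, edgeR called 0, with 556 at an unadjusted p under 0.05.

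Animals after hibernation were compared with summer active ones, the 2 ends of the cycle. In EDL 1410 genes were called, with 692 higher and 718 lower in POST. Their median log2 fold changes were 0.85 and -0.99, and 616 of the 1410 genes changed more than 2-fold. In SOL 143 genes were called, 66 higher and 77 lower, with medians of 1.29 and -1.57. Called in both muscles were 45 higher and 40 lower genes, where independent lists would share 2.78 and 3.31, and 0 were called in opposite directions. Those lists ignore that same-numbered libraries deviate together. Of the genes called in EDL, 98.4% had the same sign in SOL, against 76.7% of all 16007 genes. The fold changes of the muscles correlated across genes at r = 0.66, and at up to 0.63 in other splits of the paired libraries, with a covariance of 0.324 against at most 0.196. A test of the difference between the muscles, chosen after seeing these counts, called 0 genes by edgeR, with 612 at an unadjusted p under 0.05 and, with same-numbered libraries paired, 0 genes and 1507. None of the 4 followed identifiers passed the threshold in POST against SA in either muscle.

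The SOL count of POST against SA moved widely when single libraries were left out. A group of 2 libraries has less power in any comparison, and the fall from that alone was not measured. It was 10, 179 and 2137 without POST replicates 1, 2 and 3, and 19, 6 and 2 without SA replicates 1, 2 and 3. The EDL count was 861, 663 and 561 without POST replicates 1, 2 and 3, and 411, 1423 and 239 without SA replicates 1, 2 and 3. With the spread estimated from the 6 compared libraries alone, 283 genes were called in EDL and 0 in SOL by edgeR, where 1890 had an unadjusted p under 0.05 and DESeq2 on all 15 libraries called 1441.

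**Figure D4:**
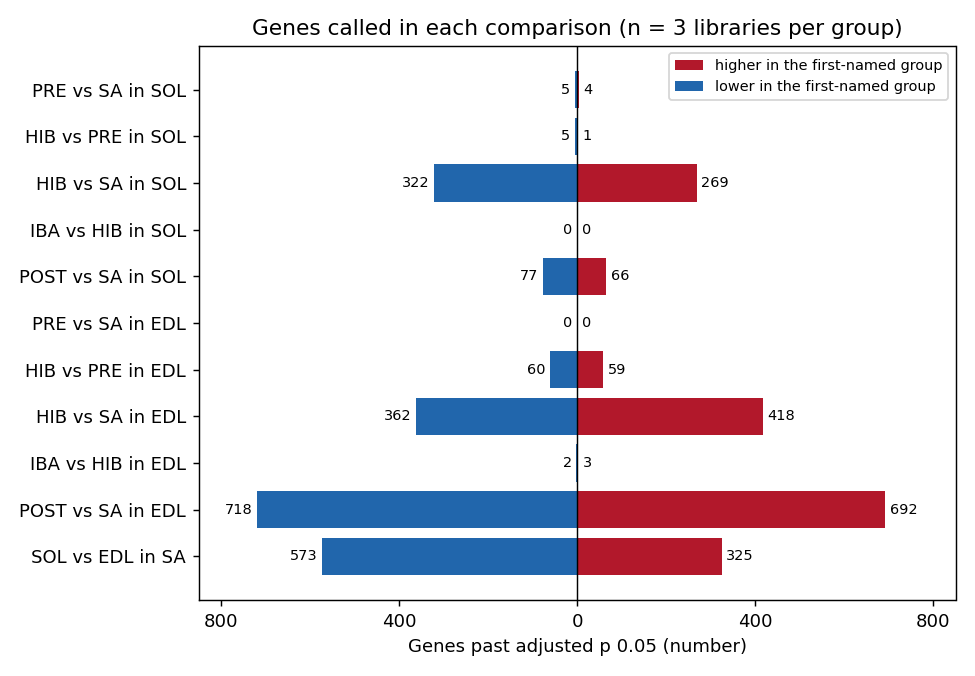
Number of genes past an adjusted p of 0.05 in edgeR, higher (right) and lower (left) in the first-named group, for 11 comparisons of 3 libraries with 3. Among those drawn, POST against SA in EDL has the most genes, 692 higher and 718 lower, and IBA against HIB has at most 3 in a direction.

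The 2 muscles were compared in summer active animals, without hibernation. Of 16946 genes tested, 898 were called, 325 higher in SOL with a median log2 difference of 2.20 and 573 higher in EDL with a median of -1.26. Differences of more than 2-fold were found for 272 and 372 of them. The largest towards EDL was -12.5 on the log2 scale, and the largest towards SOL was 8.09. With same-numbered libraries paired, 2215 genes were called, 917 higher in SOL and 1298 higher in EDL, of which 881 were among the 898. The unpaired count was 570 without SA SOL replicate 1 and 523 without SA EDL replicate 2. The 4 identifiers followed above did not pass between the muscles, and 101963904 differed by 0.01 ± 0.41.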

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

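The alternatives without POST SOL replicate 1 in comparisons that do not hold it, the thinned counts and all settings of the set tests were chosen after seeing the data, and the others were fixed before. The 4 identifiers given by number kept their direction between HIB and SA in every setting run for them. Counts near the threshold moved widely, for causes that were not tested. Fits with fewer libraries have less power, and the fall from that alone was not measured. The share of called genes that were higher moved too, so it gives no direction to a comparison as a whole. Over all settings with calls it ran, for HIB against SA, from 18.7% (without SA replicate 1) to 63.2% (without HIB replicate 1) around 45.5% in SOL, and from 45.4% to 61.3% around 53.6% in EDL. For POST against SA it ran from 0% (2 genes, without SA replicate 3) to 54.3% around 46.2% in SOL, with 21.9% under the block across states, and from 35.0% to 54.2% around 49.1% in EDL. It ran from 12.5% to 63.4% around 49.6% for HIB against PRE in EDL, and from 32.5% to 46.9% around 36.2% for SOL against EDL in SA. Medians near 0 of sets that did not pass in the main fit changed sign without 1 library: for genes higher in EDL in SA, POST against IBA in SOL went from -0.03 to 0.06 without POST replicate 3 and to 0.05 without IBA replicate 2, and IBA against HIB in SOL from 0.08 to -0.01 without IBA replicate 2. For genes higher in SOL in SA, IBA against HIB in EDL went from 0.04 to -0.01 without IBA replicate 3. Some of the sets that did not pass in the main fit passed camera without another library. For genes higher in EDL in SA, POST against IBA in SOL then had a median of -0.16 without POST replicate 1 (camera adjusted p = 6.19e-06) and -0.05 without IBA replicate 3 (camera adjusted p = 0.0471), IBA against HIB in SOL one of 0.13 without IBA replicate 1 (camera adjusted p = 0.0383) and 0.11 without IBA replicate 3 (camera adjusted p = 0.00572), and HIB against PRE in SOL one of -0.09 without PRE replicate 3 (camera adjusted p = 0.0376). For genes higher in SOL in SA, HIB against PRE in SOL had a median of -0.05 without PRE replicate 2 (camera adjusted p = 0.0378) and -0.11 without HIB replicate 2 (camera adjusted p = 0.0258), and it also passed with no filter on low counts (camera adjusted p = 0.0346) and in fry (fry adjusted p = 0.0349). The estimated correlation was not run with libraries left out. The tests of gene lists were not run under any setting, since the identifiers carry no names. DESeq2's size factors moved no count by over 1.5 times. With every library thinned to 31442362 counts, the lowest total, POST against SA called 132 genes in SOL and 1420 in EDL. Thinning was not run for the other comparisons, and totals differ too little for it to show what deeper sequencing would add.

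With DESeq2's Wald test, SOL gave 1073 genes for PRE against SA, 369 for HIB against PRE, 1959 for HIB against SA, 41 for IBA against HIB and 1441 for POST against SA. EDL gave 539, 1072, 1727, 134 and 2417 in the same order, and SOL against EDL in SA gave 1351. With no filter on low counts, SOL gave 17 for PRE against SA, 1 for IBA against HIB and 92 for POST against SA, and EDL gave 11 for PRE against SA and 9 for IBA against HIB. With all 30 libraries in 1 fit, SOL gave 721, 112, 1563, 7 and 1084 in the order above, and EDL gave 3 for PRE against SA. With only the libraries of the compared groups, SOL gave 424 for PRE against SA, 95 for HIB against PRE, 1353 for HIB against SA and 0 for POST against SA. EDL then gave 265 for HIB against SA, 2 for IBA against HIB and 283 for POST against SA.

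With the replicate number as a block across states, where numbers are not pairs, SOL gave 1, 1, 329, 1 and 32 in the order above, and EDL gave 41 for HIB against PRE and 1 for IBA against HIB. The block on the number within a state, where numbers pair SOL with EDL, gave 2215 for SOL against EDL in SA, and both tests of a difference between the muscles stayed at 0 under every block, filter, scaling and tool run.

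Leaving out 1 library gave, in SOL, 1 to 979 genes for PRE against SA, 0 to 12 for HIB against PRE, 6 to 1616 for HIB against SA, 0 throughout for IBA against HIB and 2 to 2137 for POST against SA. In EDL it gave 0 to 58, 2 to 41, 89 to 416, 1 to 6 and 239 to 1423 in the same order. For SOL against EDL in SA it gave 523 to 1206, and 0 for both differences between the muscles. The highest values for PRE against SA, HIB against PRE and HIB against SA in SOL, and for SOL against EDL in SA, came without POST SOL replicate 1.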

Other observations

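The set tests and further comparisons below, and the tests on depth, on abundant genes, on carried RNA, on the state label, on leaving out POST SOL replicates 1 and 3, on numbers across states and on best matches, were chosen after the result they bear on was seen. Genes that set HIB apart from SA were looked up in comparisons of other states, whose libraries shared the estimate of spread that decided which genes passed. In EDL, the 418 genes higher in HIB than SA were also higher in POST than in PRE, with a median log2 difference of 0.38 and 86.6% of them above 0 (camera adjusted p = 1.09e-21 over 20 set tests; adjusted p = 0.0293 with an estimated correlation). Of these, 43 were called higher and 1 lower when adjusted over the list alone, and 4 higher and 0 lower when adjusted over all genes. In the same fit this call, and that of the lower genes below, held in all 11 alternatives run for each, single libraries left out included. The filter, scaling, block and left-out fits used the preset correlation of 0.01, against estimates of 0.0852 and 0.0553 for these sets. With the estimated correlation no library was left out. The 362 genes lower in HIB than SA were lower in POST than in PRE, with a median of -0.27 and 20.4% above 0 (camera adjusted p = 7.06e-14; adjusted p = 0.0293 with an estimated correlation). In SOL the 269 genes higher in HIB had a median of 0.18 in POST against PRE (camera adjusted p = 2.18e-08), a call lost at an adjusted p = 0.0943 with an estimated correlation. The 322 genes lower in HIB had a median of -0.11 (camera adjusted p = 0.00541; adjusted p = 0.445 with an estimated correlation). That median was -0.01 without POST SOL replicate 1 (camera adjusted p = 0.789, against 3.61e-04 to 0.445 in the other alternatives), -0.16 without POST replicate 2 and -0.22 without POST replicate 3. IBA against PRE uses the same PRE libraries as POST against PRE, so its results are not independent of those above. In IBA against PRE the genes higher in HIB had medians of 0.23 in SOL (camera adjusted p = 6.83e-09) and 0.27 in EDL (camera adjusted p = 8.90e-11), both at an adjusted p = 0.0943 with an estimated correlation. The genes lower in HIB had medians of 0.05 in SOL (camera adjusted p = 0.494), opposite in sign to their change in HIB, and -0.12 in EDL (camera adjusted p = 3.93e-04; adjusted p = 0.208 with an estimated correlation). The EDL median was -0.08 without PRE replicate 2 and -0.06 without IBA replicate 2, and the SOL median 0.09, 0.11 and 0.00332 without PRE replicate 3, IBA replicate 2 and IBA replicate 3.

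The sets were also called from the 6 HIB and SA libraries of a muscle alone and tested in a fit of the PRE, IBA and POST libraries alone, as 8 further tests. In EDL the 143 tested genes higher in HIB had a median of 0.49 in POST against PRE, with 86.7% above 0 (camera adjusted p = 1.87e-16), and the 120 lower genes a median of -0.27, with 30.8% above 0 (camera adjusted p = 7.38e-08). Neither passed with an estimated correlation (adjusted p = 0.257 for both). In SOL the medians were 0.18 for 562 higher genes (camera adjusted p = 1.22e-06) and -0.06 for 770 lower genes (camera adjusted p = 0.0116), with adjusted p = 0.257 and 0.605 with an estimated correlation. Without single libraries the SOL medians ran from 0.07 to 0.26 and from -0.23 to 0.13, and the EDL medians from 0.33 to 0.65 and from -0.40 to -0.16. For IBA against PRE, with the same PRE libraries again, the higher and lower genes had medians of 0.12 and 0.15 in SOL and 0.47 and -0.26 in EDL. With an estimated correlation none of these 4 passed, at adjusted p = 0.299, 0.642, 0.257 and 0.285 in that order.

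Genes that part the muscles in SA were followed in the same way, in fits that shared the estimate of spread. In EDL, the 573 genes higher in EDL had a median of -0.22 in HIB against PRE (camera adjusted p = 4.04e-06) and of 0.20 in POST against IBA (camera adjusted p = 2.57e-06), each at an adjusted p = 0.208 with an estimated correlation. In SOL, the 325 genes higher in SOL were higher in POST than in IBA, with a median of 0.16 and 61.2% above 0 (camera adjusted p = 2.68e-04; adjusted p = 0.0293 with an estimated correlation), the only one of these 12 tests to pass with it. In EDL the same comparison went the other way for genes higher in SOL, with a median of -0.20 in 302 genes and 33.8% above 0 (camera adjusted p = 0.00133; adjusted p = 0.160 with an estimated correlation). In IBA against HIB, the genes higher in SOL had a median of -0.10 in SOL (camera adjusted p = 0.0329; adjusted p = 0.0943 with an estimated correlation), and the genes higher in EDL one of 0.09 in EDL (camera adjusted p = 0.0215; adjusted p = 0.584 with an estimated correlation). The first median was -0.05 and -0.03 without HIB replicates 1 and 2, and its call was lost without HIB replicate 2, IBA replicate 1 or IBA replicate 2. The second was 0.03 without IBA replicate 2, and its call was lost without that library, HIB replicate 2 or HIB replicate 3. The other 6 tests did not pass camera. The count of genes called between SOL and EDL was 898 in SA, 658 in PRE, 524 in HIB, 392 in IBA and 1426 in POST. With same-numbered libraries paired, the counts were 2215, 1685, 1422, 1139 and 3084 in that order. Whether these counts differ between states was not tested as such.

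Sums of both muscles per number gave 15 libraries and 594 genes for PRE against SA, 121 for HIB against PRE, 1388 for HIB against SA, 3 for IBA against HIB and 1782 for POST against SA. Without POST number 1 the same sums gave 910, 151, 1808, 2 and 519. IBA against SA called 19 genes in SOL and 18 in EDL, and 130 in SOL without POST SOL replicate 1. POST against HIB called 2 in SOL and 35 in EDL, and 0 in SOL without that library, where 1450 had an unadjusted p under 0.05.

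POST SOL replicate 1 lay apart from the other 14 SOL libraries. Low depth does not account for it, since its total was 1.07 times the median of the others, which ran from 0.937 to 1.20 times. Its 50 most abundant identifiers took 36.7% of its counts and its TMM factor was 0.733, the highest share and the lowest factor in SOL. A few abundant genes taking counts would shift all other genes by 1 factor. Around its median shift the other 5448 genes of high counts spread by 0.477 on the log2 scale (scaled MAD). The other libraries had at most 0.383 (SD between them 0.0543). A library that lies apart for any cause would spread more, so this adds little. Its gap to the nearest library on the first component was 0.516 of the range, and 0.514 without its 50 most abundant identifiers. That argues against those identifiers as the whole of the gap. Its muscle score of -0.0707 was far above the highest EDL library, at -2.88, which argues against a wrong muscle label. A wrong state label cannot be told apart from a real difference: its highest correlation with another state was 0.952, with PRE, against 0.947 with its own, while the own-state correlations of the others had a median of 0.976 and a lowest value of 0.952. A difference of this animal or of its sample stays open and was not tested.

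Fewer genes were called for POST against SA in SOL than in EDL, 143 against 1410. The size of this gap depends on the fit. With all 30 libraries in 1 fit SOL gave 1084 genes, and DESeq2 gave 1441 in SOL and 2417 in EDL. Whether the spread of POST SOL replicate 1 accounts for the gap cannot be told. Without it SOL fell to 10 genes, but that fit kept 2 POST libraries and lost the one farthest from SA on the first component. Leaving out SA replicates 1, 2 and 3 also cut the count, to 19, 6 and 2. Where POST SOL replicate 1 is in neither group, leaving it out raised SOL counts from 9 to 979 for PRE against SA. For HIB against SA they rose from 591 to 1616, and IBA against HIB stayed at 0. Without POST SOL replicate 3 SOL rose to 2137 genes, which rest on replicate 1, the library that stood apart, and on replicate 2. Whether replicate 3 differs from these cannot be told apart from other causes, since replicates 1 and 2 correlated at 0.942, 1 and 3 at 0.927 and 2 and 3 at 0.950. All 3 POST SOL libraries had lower mean correlations with their own group, 0.935 to 0.946, than any other SOL library, at 0.958 to 0.973. The POST EDL libraries had 0.963 to 0.965. A wider scatter of the whole POST SOL group was not tested as a cause of the gap. Depth does not account for the gap, with a ratio of 10.8 between EDL and SOL after thinning. A real difference between the muscles stays open, since the test of that difference called 0 genes, which does not show that the muscles change alike.

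Same-numbered SOL and EDL libraries of a state deviated together. A batch that follows the number across states does not account for it, as the median correlation of same-numbered libraries in other states was -0.00885. Over 3007 genes with large p-values in the unpaired tests between the muscles the median correlation was 0.57, from 0.32 to 0.74. Such p-values do not show that the muscles are equal. They also favour genes whose 2 muscles deviate together, so part of the rise over the median of 0.44 in all genes may come from this choice. RNA carried from one muscle into the other was weighed by the share it would need. An exchange both ways between unrelated libraries of equal spread would need a share of 0.237 for the median of 0.57, and less for a lower median. Genes abundant in the other muscle bounded the share at 0.0117 to 0.126 in the 30 libraries. The bound is a ratio near the lowest among these genes, not the lowest itself. The lowest ratio, which rests on a single gene per library, ran from 0 in PRE SOL 2 to 0.0457 in IBA EDL 1. A carried share could not exceed it, apart from errors in that gene's counts. By the limit set for this test, the bound of 0.126 was too close to 0.237 to decide. With the bound taken out of each library the median correlation over the same genes was 0.51, from 0.26 to 0.67. These values argue against an exchange as the whole of the pattern in these genes, and an exchange as a part of it stays open. All 30 libraries matched their own number best. Both muscles coming from one animal would give this, and so could a smaller exchange. A shared day of sampling or library preparation within a state was not tested.

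Splits of the 6 libraries of each comparison into other groups of 3 are 10 with the real one, too few for a share under 0.05. In 9 comparisons the real split was the 1 with the most genes, and the highest other split is given after it. The values were 9 and 0 for PRE against SA, 6 and 0 for HIB against PRE, 591 and 0 for HIB against SA and 143 and 23 for POST against SA in SOL. In EDL they were 119 and 1 for HIB against PRE, 780 and 0 for HIB against SA, 5 and 1 for IBA against HIB and 1410 and 0 for POST against SA. For SOL against EDL in SA they were 898 and 2, and the 3 other splits that part all 3 same-numbered pairs gave 0. IBA against HIB in SOL and PRE against SA in EDL called 0 genes in all 10 splits. For the differences between the muscles, all 100 splits drawn gave at least the 0 genes of the real one, which any split must, so they say nothing about chance. Their highest counts were 3991 for HIB against SA and 358 for IBA against HIB, each from the split that exchanged the state labels in EDL only, which adds the changes of the 2 muscles up.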
